A study of Rattus norvegicus with 18 samples.

How the data were processed

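Poly(A) RNA of the rat line H9C2 was measured in 18 libraries, 3 in each of 6 groups (NC without treatment, ES10 with 10 pulses, ES50 with 50 pulses, P with PE, P_ES10 and P_ES50 with PE and 10 or 50 pulses). Groups and replicate numbers come from the sample labels. Per the labels' protocols, 1 µg of RNA entered each library, mRNA was captured on poly-T beads, and cDNA was primed with random hexamers. The time from the pulses to harvest and the strandedness of the libraries are not given in the sources used here, nor is what PE stands for. The genome build is Rnor 6.0, per the submitters' processing notes, and the aligner, the counting tool and the annotation release are not given in the sources used here.

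The deposited values are FPKM per gene for 32545 genes, with gene identifiers, symbols, positions and lengths, and 1 column per library. FPKM times gene length gave whole multiples of 1 step per library for 100% of genes (tolerance 0.01 of a read), so the reads behind each deposited value could be recovered, at 14004929 to 17247201 per library. The median ratio of a library to the geometric mean library was 1.009 in all 18 libraries, which is what a library term made of median ratios gives. The deposited FPKM therefore set the median gene equal between libraries, whatever share of the reads a few genes take. ES50 libraries held 1230554 to 1466851 reads on nuclear genes, so low nuclear genes are measured there with less precision. Floors for genes without reads cover counting error only.

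Genes with an FPKM of at least 1 in at least 3 libraries were kept, which left 11917. Values were tested as log2(FPKM + 1) with limma 3.58.1 (lmFit, contrasts.fit and eBayes with a mean-variance trend) in R 4.3.3, in 1 model of the 6 group means fitted to all 18 libraries. A fold change on this scale understates the change of low genes. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and an adjusted p under 0.05 was called. The contrasts were ES10 and ES50 versus NC, ES50 versus ES10, P versus NC, P_ES10 and P_ES50 versus P, P_ES50 versus P_ES10, and 2 interactions, the response to 10 or 50 pulses with PE minus that without. P_ES10 versus ES10 and P_ES50 versus ES50 were added after the data were seen. Library measures were compared by exact two-sided permutation tests, for which 3 against 3 gives a smallest p of 0.1. Data were read with the R package data.table (version 1.17.8), and tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

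Before the data were examined, the model, the alternatives, the gene lists and the rule for named genes were fixed. The 39 lists cover mitochondrial and energy metabolism genes, cell death, stress responses, cell cycle, muscle and calcium genes, matrix, signalling targets, lipid synthesis, membrane repair, ribosome genes, histones and markers of 6 cell types. Of these, 36 had at least 3 tested members and were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists within each contrast. Camera with an estimated correlation was run beside it, and fry, which asks whether the members of a list change on balance in 1 direction and does not compare them with other genes. Median, mean and test of a list differed in sign in 53 of 396 results, of which 0 passed the threshold. Several lists share members, so their results are not independent.

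Named genes follow the fixed rule. For each response to pulses or PE against its own control they are the 10 largest increases and the 10 largest decreases among called genes whose 3 libraries do not overlap with the other 3, and 5 of each for the other contrasts, without the overlap condition for the interactions. To these come up to 4 members of each list with the smallest adjusted p, and 20 genes fixed in advance. Genes without a proper symbol were left out, and not every gene under the rule is named. The symbol Mt1 occurs for more than 1 gene and was left out. For the 2 comparisons added later, genes were named by the rule for the other contrasts.

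Reads of near-identical genes may be split or lost in counting. This concerns Hspa1b and Hspa1a, ribosomal protein genes and their pseudogenes, and mitochondrial genes and their nuclear copies. Mt-atp8 and Mt-atp6, and Mt-nd4l and Mt-nd4, overlap, and without strand the reads of Mt-nd5 and Mt-nd6 at their shared end cannot be told apart.

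The steps were tested on simulated data drawn from the real means and library sizes. For ES10 versus NC, 46.9%, 77.1%, 92% and 96% of genes changed 1.5-, 2-, 4- and 8-fold were recovered among 11732 genes, and 0.0434% of 11511 unchanged genes were called. For ES50 versus NC the shares were 54.2%, 75%, 89.6% and 96% among 11670 genes, with 0.786% of 11452 unchanged genes called. Only 48, 48, 48 and 50 genes changed 1.5-, 2-, 4- and 8-fold were tested there. With so few changed genes, the false calls were a larger part of all calls than the adjusted p threshold allows. Error control therefore failed for ES50 versus NC in this simulation. Whether it also fails in the real data, with many more calls, was not tested. For P_ES50 versus P they were 50%, 56%, 94% and 88% among 11722 genes, with 0.0870% of 11498 unchanged genes called.

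Alternatives fixed in advance were a pseudocount of 0.1, no filter or an FPKM of at least 5, rescaling by median ratios, quantile normalization, no variance trend, only the groups compared in the fit, the replicate number as a block, each library left out in turn, and sums over protein-coding genes. After the data were seen, 5 were added: scaling to total reads, limma-voom on the recovered reads, reads thinned to 1230554 nuclear reads in every library, protein-coding genes only, and a fit without the 3 ES50 libraries. Replicate pairs within a group differed by more than counting noise, with a chi-square per degree of freedom of 2.99 to 5.38 and log2 correlations of 0.949 to 0.988 across genes, so no 2 were taken as copies of a single library. This does not show that they came from separate cultures. No genome sequence was used here.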

Results

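RNA of H9C2 cells, a line derived from embryonic rat heart, was sequenced in 18 libraries that fall into 6 groups of 3. NC cells received no treatment. ES10 and ES50 cells received 10 and 50 electric pulses of 100 µs at 1500 V/cm. P cells were kept for 48 h with 50 µmol/L of a compound that the labels give only as PE, and P_ES10 and P_ES50 cells received PE and the 10 or 50 pulses. The series asks how such pulses act on the survival and activity of heart muscle cells and on their mitochondria. The libraries held 14004929 to 17247201 reads on genes, recovered from the deposited FPKM. Replicates are only numbered, so p-values measure the spread between libraries, which may be technical. The model pools the spread of a gene over all 18 libraries, so it is not that of the groups compared. ES50 replicates were less alike, with log2 correlations of 0.949 to 0.955 against 0.979 to 0.988 in the other groups. With only the groups compared in the fit, calls went from 8583 to 7071 in ES50 versus NC and from 1021 to 2246 in ES10 versus NC. FPKM are given as mean ± SD with n = 3, and changes as log2 fold change of FPKM plus 1 ± standard error, a scale that understates the change of low genes. Adjusted p-values of genes are limma's, and those of gene lists are camera's with a preset correlation. Changes are relative to the median gene, as the deposited scaling sets them. Scaling to total reads moved the median gene by -2.49 in ES50 versus NC, -2.45 in ES50 versus ES10, 0.11 in P versus NC, -0.80 in P_ES50 versus P and -0.72 in P_ES50 versus P_ES10. The shift was 1.71 for the interaction of PE and 50 pulses, and -0.04, -0.09 and -0.05 in ES10 versus NC, P_ES10 versus P and the interaction of PE and 10 pulses. Where the direction of a named gene or list flips with this scaling or after quantile normalization, the text says so.

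The share of reads on the 37 mitochondrial genes set the groups apart. It was 12.9 ± 1.21% in NC, 9.44 ± 0.319% in ES10 and 92.1 ± 0.728% in ES50. With PE it was 5.48 ± 0.104% without pulses, 6.46 ± 0.377% after 10 pulses and 48.6 ± 1.66% after 50 pulses. In each comparison of these groups the 3 libraries of one all lay on one side of the other 3, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 can give. Reads on nuclear genes were few in ES50, at 1230554 to 1466851 per library. The number of genes with an FPKM of at least 1 was 10946.7 ± 19.5 in NC and 10202.7 ± 39.0 in ES50, again with an exact p of 0.1. Ribosomal protein genes held 3.04 ± 0.0649% of nuclear reads in NC and 7.23 ± 0.235% in ES50.

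**Figure D1:**
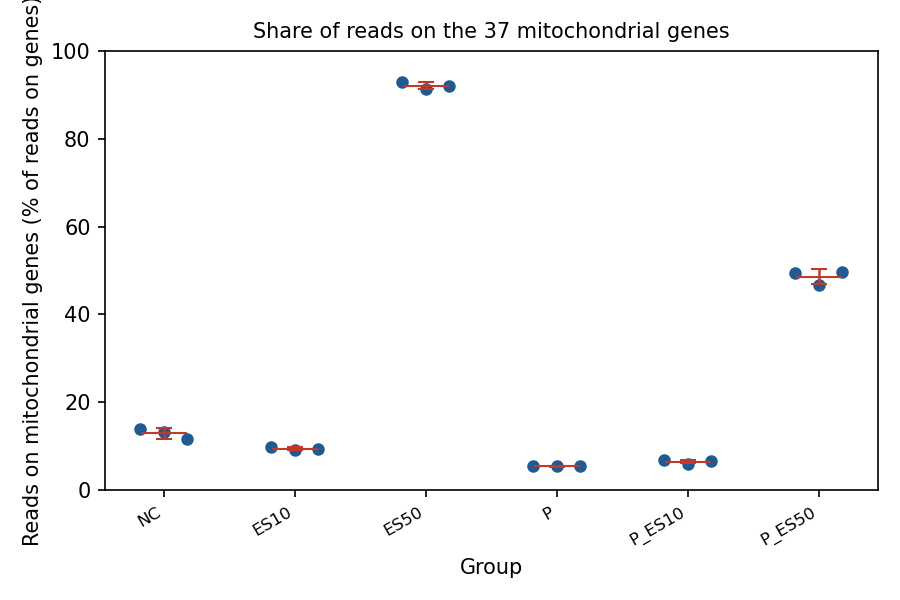
Share of reads on genes that fell on the 37 mitochondrial genes, in percent, for each of the 18 libraries in 6 groups (points), with the group mean and SD (red bars). The 3 ES50 libraries averaged 92.1% and the 3 P_ES50 libraries 48.6%, against 12.9% in NC and 5.48% in P.

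In cells without PE, 10 pulses raised heat shock genes, NRF2 targets and genes of cholesterol synthesis, and lowered mitochondrially encoded mRNAs. Under the rule for named genes, Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1, rose most (ENSRNOG00000014117, chromosome 19, 14508616 to 14515456, build Rnor 6.0). Its level was 329 ± 10.3 FPKM in NC and 1152 ± 98.1 in ES10, a log2 fold change of 1.80 ± 0.08 with an adjusted p of 1.97e-08. Hspa1b, an inducible heat shock protein gene, rose from 1.83 ± 0.206 to 6.52 ± 1.14 FPKM (1.40 ± 0.18, adjusted p = 1.70e-04), though its reads may be split with the near-identical Hspa1a. Adm, the gene of the vasodilator peptide adrenomedullin, went from 12.1 ± 0.366 to 29.0 ± 2.24 FPKM (1.19 ± 0.08), and Myadm rose by 1.24 ± 0.07. Among the largest decreases under that rule were Mcam, a cell adhesion molecule, at -0.94 ± 0.21, Nrep at -0.93 ± 0.17 and the sulfotransferase gene Chst2 at -0.90 ± 0.14.

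Among genes of cholesterol synthesis, 11 rose and 0 fell of 24 tested (15 and 0 adjusted over the list alone, median 0.40, adjusted p = 2.18e-14). Idi1 rose by 1.05 ± 0.07, Hmgcs1 by 0.78 ± 0.05 and Cyp51 by 0.63 ± 0.06. In the heat shock list 8 rose and 0 fell of 15 tested (10 and 1 adjusted over the list alone, median 0.23, adjusted p = 2.13e-08), and the chaperone genes Hsph1, Bag3 and Hsp90ab1 rose by 0.48 ± 0.05, 0.43 ± 0.05 and 0.29 ± 0.03. Of the antioxidant targets of NRF2, 6 rose and 0 fell of 18 tested (9 and 0 adjusted over the list alone, median 0.21, adjusted p = 3.32e-07). Txnrd1 was at 0.56 ± 0.04 and Prdx1 at 0.31 ± 0.04 after Hmox1. Immediate early genes moved alike: 12 rose and 1 fell of 26 tested (14 and 1 adjusted over the list alone, median 0.35, adjusted p = 9.27e-07 but adjusted p = 0.0613 with an estimated correlation). Fosb was at 1.06 ± 0.13, Fosl1 at 1.00 ± 0.08, Fos at 0.68 ± 0.12 and Egr1 at 0.55 ± 0.14. For glycolysis 5 rose and 0 fell of 17 tested (7 and 0 adjusted over the list alone, median 0.12, adjusted p = 0.00259). The hexokinase gene Hk2 was at 0.49 ± 0.06. For autophagy and lysosome genes 6 rose and 0 fell of 25 tested (8 and 0 adjusted over the list alone, median 0.11, adjusted p = 0.0011). Sqstm1 was at 0.30 ± 0.05. For cardiac hypertrophy markers 4 rose and 1 fell of 10 tested (4 and 1 adjusted over the list alone, median 0.13, adjusted p = 0.00403). Ankrd1 was at 0.45 ± 0.06. Of the mitochondrially encoded mRNAs, 0 rose and 11 fell of 13 tested (0 and 13 adjusted over the list alone, median -0.46, adjusted p = 6.87e-16). Mt-nd4l was at -0.68 ± 0.09, Mt-nd5 at -0.64 ± 0.05 and Mt-cytb at -0.48 ± 0.07.

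The other called lists lost the call with an estimated correlation. In the G2/M and mitosis list 1 rose and 5 fell of 27 tested (1 and 6 adjusted over the list alone, median -0.14, adjusted p = 3.51e-04 but adjusted p = 0.0613 with an estimated correlation). Cdc20 was at -0.49 ± 0.10 and Kif20a at -0.31 ± 0.07. Of the p53 targets 5 rose and 1 fell of 21 tested (6 and 2 adjusted over the list alone, median 0.10, adjusted p = 0.0184 but adjusted p = 0.0613 with an estimated correlation). Plk2 was at 0.54 ± 0.04 and Gadd45a at 0.53 ± 0.05. Of the calcium handling and ion channel genes 2 rose and 0 fell of 16 tested (4 and 0 adjusted over the list alone, median 0.16, adjusted p = 0.00403 but adjusted p = 0.0613 with an estimated correlation). Atp1b1 was at 0.45 ± 0.07. The other 3, extracellular matrix, ribosome biogenesis and the unfolded protein response of the endoplasmic reticulum (ER), had medians of 0.095, 0.12 and 0.057, the last at -0.0055 after quantile normalization, with adjusted p = 0.225, 0.0815 and 0.0815 with an estimated correlation. Their members Thbs1, Myc and Dnajb9 were at 0.39 ± 0.06, 0.96 ± 0.16 and 0.51 ± 0.08.

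Apoptosis genes of the BCL2 family were not called as a list, where 1 rose and 0 fell of 22 tested (2 and 2 adjusted over the list alone, median -0.11, adjusted p = 0.273). Bax changed by 0.16 ± 0.06 (adjusted p = 0.127) and Bcl2 by 0.08 ± 0.20 (0.895). The same was true of mitochondrial dynamics and mitophagy, where 0 rose and 0 fell of 17 tested (0 and 0 adjusted over the list alone, median 0.044 but -0.027 after quantile normalization, adjusted p = 0.867), and of regulators of mitochondrial biogenesis, where 0 rose and 1 fell of 8 tested (0 and 1 adjusted over the list alone, median -0.055, adjusted p = 0.423). For membrane repair 6 rose and 1 fell of 24 tested (9 and 1 adjusted over the list alone, median 0.02 but -0.018 with scaling to total reads and -0.056 after quantile normalization, adjusted p = 0.0842), and for necroptosis, pyroptosis and ferroptosis 1 rose and 1 fell of 15 tested (3 and 3 adjusted over the list alone, median 0.031 but -0.0053 with scaling to total reads and -0.0011 after quantile normalization, adjusted p = 0.968).

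In limma's model of all 18 libraries, 1021 of 11917 tested genes passed an adjusted p of 0.05, with 758 higher and 263 lower, of which 23 and 5 changed at least 2-fold. Scaled to total reads 920 were higher and 761 lower, and after quantile normalization 699 and 534. Without the 3 ES50 libraries in the fit 2574 genes passed, on reads thinned to the same nuclear depth 313 did, and with any of the 6 libraries left out between 580 and 650 did.

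After 50 pulses without PE, mitochondrially encoded mRNAs took most of the reads, and among nuclear genes those of the extracellular matrix, cytokines and the ER fell. Mt-nd3 rose from 3157 ± 426 to 449957 ± 16522 FPKM (7.16 ± 0.08, adjusted p = 3.36e-18), Mt-nd1 by 6.64 ± 0.06 and Mt-cytb by 6.28 ± 0.07. Adgre5, an adhesion receptor gene (ENSRNOG00000004489, chromosome 19, 24855299 to 24875137), fell from 74.5 ± 2.96 to 1.28 ± 1.17 FPKM (-5.17 ± 0.22), with 28 reads left in the 3 ES50 libraries. The collagen genes Col3a1 (ENSRNOG00000003357, chromosome 9, 52023295 to 52059217) and Col1a1 changed by -3.09 ± 0.04 and -2.55 ± 0.03, and the fibronectin gene Fn1 by -2.40 ± 0.03. Ankrd1, a cardiac ankyrin repeat gene, rose from 66.8 ± 3.29 to 1048 ± 21.0 FPKM (3.95 ± 0.06, and 0.42 with scaling to total reads).

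Of the mitochondrially encoded mRNAs, 13 rose and 0 fell of 13 tested (13 and 0 adjusted over the list alone, median 6.53, adjusted p = 2.44e-13), and with scaling to total reads their median was 2.99. In these libraries with 92.1% mitochondrial reads, the nuclear lists that fell were led by the extracellular matrix, where 0 rose and 20 fell of 20 tested (0 and 20 adjusted over the list alone, median -2.34, adjusted p = 8.16e-11). Of the NF-kB and cytokine genes, 0 rose and 14 fell of 15 tested (0 and 14 adjusted over the list alone, median -2.19, adjusted p = 6.50e-06). Ptgs2, an inducible prostaglandin synthase, was at -3.20 ± 0.11, the cytokine gene Lif at -3.43 ± 0.13 and the adhesion gene Icam1 at -2.64 ± 0.13. Of the fibroblast markers, 0 rose and 6 fell of 6 tested (0 and 6 adjusted over the list alone, median -1.67, adjusted p = 0.00206). Among hypoxia targets 1 rose and 12 fell of 14 tested (1 and 12 adjusted over the list alone, median -1.83, adjusted p = 2.67e-04). Hk2 was at -2.47 ± 0.06, Vegfa at -2.33 ± 0.07 and Adm at -2.87 ± 0.08. In the unfolded protein response of the ER 1 rose and 16 fell of 19 tested (1 and 16 adjusted over the list alone, median -0.98, adjusted p = 7.25e-05). Sel1l was at -2.11 ± 0.07 and Hsp90b1 at -1.23 ± 0.04. Of the genes of the ATF4 integrated stress response, 2 rose and 16 fell of 21 tested (2 and 17 adjusted over the list alone, median -0.71, adjusted p = 0.00105). The amino acid transporter gene Slc7a5 was at -2.51 ± 0.05 and Slc3a2 at -1.82 ± 0.04. Hmox1 changed by -2.06 ± 0.08, to 78.8 ± 13.3 FPKM. Among immediate early genes 5 rose and 20 fell of 26 tested (5 and 20 adjusted over the list alone, median -1.0, adjusted p = 0.00341 but adjusted p = 0.216 with an estimated correlation). Dusp5 was at -3.11 ± 0.06, Fosl1 at -2.71 ± 0.08 and Junb at -1.06 ± 0.05. For ribosome biogenesis 3 rose and 21 fell of 27 tested (3 and 21 adjusted over the list alone, median -0.70, adjusted p = 0.00341 but adjusted p = 0.0681 with an estimated correlation). Gnl3 was at -1.63 ± 0.06. For calcium handling 1 rose and 11 fell of 16 tested (1 and 11 adjusted over the list alone, median -0.94, adjusted p = 0.009 but adjusted p = 0.0777 with an estimated correlation). The calcium release channel gene Itpr3 was at -2.51 ± 0.05.

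Other nuclear lists rose relative to the median gene and fell with scaling to total reads, as did each rising gene named with them here. Of the ribosomal protein genes, some of whose reads may be shared with pseudogenes, 72 rose and 0 fell of 79 tested (72 and 0 adjusted over the list alone, median 1.23 but -2.20 with scaling to total reads, adjusted p = 2.87e-23). Rplp0 was at 1.73 ± 0.04 and Rpsa at 1.52 ± 0.04. Of the nuclear genes of respiratory complex I, 31 rose and 0 fell of 31 tested (31 and 0 adjusted over the list alone, median 1.15 but -2.32 with scaling to total reads, adjusted p = 2.31e-10). Ndufa5 was at 1.16 ± 0.06 and Ndufb7 at 1.28 ± 0.07. Of complexes II to V, 40 rose and 0 fell of 42 tested (40 and 0 adjusted over the list alone, median 0.97 but -2.45 with scaling to total reads, adjusted p = 4.51e-13). Cox8a was at 1.37 ± 0.05 and Uqcrq at 1.49 ± 0.06. For the YAP and SRF targets 17 rose and 3 fell of 20 tested (17 and 3 adjusted over the list alone, median 1.18 but -2.30 with scaling to total reads, adjusted p = 2.42e-06). Tpm1 was at 1.18 ± 0.03 and Axl at -1.54 ± 0.03. For smooth muscle markers 7 rose and 1 fell of 8 tested (7 and 1 adjusted over the list alone, median 1.19 but -2.16 with scaling to total reads, adjusted p = 0.00203). Lmod1 was at 2.53 ± 0.09. Acta2 (1.34 ± 0.03) and Tagln (1.26 ± 0.03) were also below 0 after quantile normalization (-0.24 and -0.053). In the TCA cycle 13 rose and 2 fell of 17 tested (13 and 2 adjusted over the list alone, median 0.26 but -2.88 with scaling to total reads, adjusted p = 0.0043). Idh2 was at 1.26 ± 0.08 and Suclg1 at 1.16 ± 0.05. In the G1/S and DNA replication list 15 rose and 3 fell of 27 tested (15 and 3 adjusted over the list alone, median 0.24 but -2.62 with scaling to total reads, adjusted p = 0.00811). E2f1 was at 1.35 ± 0.10 and Mcm5 at 0.74 ± 0.06.

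BCL2 family genes went both ways without a call for the list, where 11 rose and 8 fell of 22 tested (11 and 8 adjusted over the list alone, median 0.37 but -2.52 with scaling to total reads, adjusted p = 0.179). Bax was at 1.02 ± 0.06 (but -2.43 with scaling to total reads), and Bcl2 at -1.64 ± 0.20. For mitochondrial dynamics and mitophagy 6 rose and 5 fell of 17 tested (6 and 5 adjusted over the list alone, median -0.081 but 0.021 after quantile normalization, adjusted p = 0.359). Dnm1l was at -0.23 ± 0.08. Vdac1, a channel gene of the mitochondrial outer membrane, was at 0.38 ± 0.07, but -2.95 with scaling to total reads. Of the replication-dependent histones, 2 rose and 4 fell of 17 tested (1 and 3 adjusted over the list alone, median 0.10 but -1.33 with scaling to total reads, adjusted p = 0.876), with 2 members without reads in ES50 and a median of 0.19 with these at 3 reads over the group. The linear model called 8583 genes, 3802 higher and 4781 lower, of which 1360 and 2030 changed at least 2-fold, against 34 higher and 11471 lower with scaling to total reads.

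ES50 was also compared with ES10, which differs from it by the number of pulses. Mt-nd3 rose by 7.38 ± 0.08 and Mt-nd6 by 7.17 ± 0.10. Hmox1 was at 1152 ± 98.1 FPKM in ES10 and 78.8 ± 13.3 in ES50 (-3.86 ± 0.08), and Adm (-4.06 ± 0.08) and the chemokine gene Cxcl1 (-5.28 ± 0.47) fell as well. In the extracellular matrix list 0 rose and 20 fell of 20 tested (0 and 20 adjusted over the list alone, median -2.45, adjusted p = 1.88e-10). Of the ribosomal protein genes, 72 rose and 0 fell of 79 tested (72 and 0 adjusted over the list alone, median 1.19 but -2.20 with scaling to total reads, adjusted p = 3.07e-22). In all, 8853 genes passed limma's threshold, 3932 higher and 4921 lower, against 36 higher and 11479 lower with scaling to total reads.

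PE without pulses raised the YAP targets Cyr61 and Ctgf and lowered mitochondrially encoded mRNAs, immediate early genes and genes of the ATF4 response. Cyr61, the gene of a secreted matrix protein (ENSRNOG00000014350, chromosome 2, 251529354 to 251532312), rose from 36.9 ± 1.02 to 112 ± 1.57 FPKM (1.57 ± 0.06, adjusted p = 1.77e-09). Its relative Ctgf went from 37.8 ± 0.520 to 84.8 ± 2.41 FPKM (1.15 ± 0.07). Hmox1 went from 329 ± 10.3 to 149 ± 4.85 FPKM (-1.14 ± 0.08), and Adm changed by -1.10 ± 0.08. Acta1, the skeletal alpha-actin gene, changed by -0.91 ± 0.09, and Nppb, a natriuretic peptide gene, by 0.52 ± 0.16 with an adjusted p of 0.0514.

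Of the mitochondrially encoded mRNAs, 0 rose and 13 fell of 13 tested (0 and 13 adjusted over the list alone, median -1.35, adjusted p = 1.35e-37). Mt-nd1 was at -1.37 ± 0.06, Mt-cytb at -1.34 ± 0.07 and Mt-nd5 at -1.31 ± 0.05. Of the ATF4 response genes, 0 rose and 12 fell of 21 tested (0 and 16 adjusted over the list alone, median -0.37, adjusted p = 7.03e-14). Trib3 was at -0.82 ± 0.08 and Psat1, an enzyme of serine synthesis, was at -0.38 ± 0.04. Among immediate early genes 0 rose and 11 fell of 26 tested (0 and 19 adjusted over the list alone, median -0.36, adjusted p = 4.51e-12). Fosb was at -1.21 ± 0.13, Fos at -1.11 ± 0.12, Egr1 at -1.02 ± 0.14 and Dusp5 at -0.54 ± 0.06. Of the NRF2 targets, 0 rose and 5 fell of 18 tested (0 and 9 adjusted over the list alone, median -0.23, adjusted p = 2.68e-08). The cystine transporter gene Slc7a11 was at -0.79 ± 0.10 and Txnrd1 at -0.28 ± 0.04, but -0.17 and not called with scaling to total reads. Among genes of cholesterol synthesis, 0 rose and 7 fell of 24 tested (0 and 10 adjusted over the list alone, median -0.20, adjusted p = 6.20e-07). Idi1 was at -0.78 ± 0.07 and Insig1 at -0.68 ± 0.08. Of the p53 targets 1 rose and 7 fell of 21 tested (1 and 8 adjusted over the list alone, median -0.13, adjusted p = 5.14e-04). Gadd45a was at -0.66 ± 0.05 and Fas at 0.51 ± 0.08. In the G2/M and mitosis list 4 rose and 0 fell of 27 tested (15 and 0 adjusted over the list alone, median 0.22, adjusted p = 9.16e-09). Cdk1 was at 0.27 ± 0.04, Kif20a at 0.32 ± 0.07 and Plk1 at 0.34 ± 0.09.

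The other 10 called lists lost the call with an estimated correlation. Of the YAP and SRF targets, 10 rose and 4 fell of 20 tested (10 and 4 adjusted over the list alone, median 0.15, adjusted p = 0.00185 but adjusted p = 0.135 with an estimated correlation). Amotl2 was at 0.66 ± 0.07 and Cnn1 at -0.51 ± 0.06. In the extracellular matrix list 5 rose and 1 fell of 20 tested (5 and 1 adjusted over the list alone, median 0.053, adjusted p = 0.0185 but adjusted p = 0.243 with an estimated correlation). Timp1 was at 0.80 ± 0.10 and Postn at 0.76 ± 0.10. In the interferon-stimulated list 3 rose and 1 fell of 16 tested (6 and 1 adjusted over the list alone, median 0.22, adjusted p = 0.00815 but adjusted p = 0.0903 with an estimated correlation). Gbp2 was at 0.49 ± 0.10. In the sarcomere and muscle differentiation list 1 rose and 3 fell of 15 tested (1 and 6 adjusted over the list alone, median -0.25, adjusted p = 0.00944 but adjusted p = 0.115 with an estimated correlation). Tnnt2 was at -0.62 ± 0.12. Of the skeletal myoblast markers, 0 rose and 1 fell of 3 tested (0 and 1 adjusted over the list alone, median -0.44, adjusted p = 0.00936 but adjusted p = 0.0937 with an estimated correlation). Myod1 was at -0.44 ± 0.06. The remaining 5, mitochondrial stress, hypoxia, glycolysis, heat shock and ribosomal proteins, had medians of -0.11, -0.11, -0.068, -0.074 and -0.083, the last 3 at 0.044, 0.038 and 0.029 with scaling to total reads, with adjusted p = 0.115, 0.0502, 0.0853, 0.167 and 0.376 with an estimated correlation.

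The model called 1136 genes, 563 higher and 573 lower, of which 16 and 31 changed at least 2-fold, against 2431 higher and 558 lower with scaling to total reads. Without the ES50 libraries in the fit 3200 genes passed limma's threshold, and on thinned reads 299 did. The count was 626, 682 or 698 without NC replicate 1, 2 or 3, and 627 or 631 without P replicate 1 or 2.

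In cells kept with PE, 10 pulses raised immediate early genes, heat shock genes and genes of cholesterol synthesis. Hmox1 rose from 149 ± 4.85 to 1035 ± 31.5 FPKM (2.79 ± 0.08, adjusted p = 3.43e-11). The AP-1 genes Fosb and Fos (ENSRNOG00000008015, chromosome 6, 109300433 to 109303299) went from 6.38 ± 0.892 to 42.0 ± 1.04 FPKM (2.55 ± 0.13) and from 8.38 ± 0.966 to 45.8 ± 2.76 FPKM (2.32 ± 0.12). Trim72, a membrane repair gene, rose by 2.22 ± 0.25, Hspa1b by 2.52 ± 0.18, Adm by 2.13 ± 0.08 and Klf4 by 1.94 ± 0.21. Nrep, Mcam, Fhod1 and Fzd2 were among the largest decreases under the rule for named genes, at -1.33 ± 0.17, -1.31 ± 0.21, -1.20 ± 0.07 and -1.12 ± 0.10.

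Among immediate early genes 18 rose and 1 fell of 26 tested (19 and 1 adjusted over the list alone, median 0.75, adjusted p = 5.87e-13), and Egr1 was at 1.73 ± 0.14. Among genes of cholesterol synthesis, 16 rose and 0 fell of 24 tested (18 and 0 adjusted over the list alone, median 0.58, adjusted p = 6.29e-12). Idi1 was at 2.10 ± 0.07, Hmgcs1 at 1.58 ± 0.05, Insig1 at 1.30 ± 0.08 and Cyp51 at 1.15 ± 0.06. In the heat shock list 11 rose and 1 fell of 15 tested (11 and 1 adjusted over the list alone, median 0.45, adjusted p = 4.19e-09). Hsph1 was at 0.70 ± 0.05 and Hsp90ab1 at 0.46 ± 0.03. Of the NRF2 targets, 12 rose and 0 fell of 18 tested (13 and 0 adjusted over the list alone, median 0.34, adjusted p = 1.80e-08). Txnrd1 was at 0.86 ± 0.04. Of the ATF4 response genes, 11 rose and 1 fell of 21 tested (14 and 1 adjusted over the list alone, median 0.29, adjusted p = 1.21e-04). Ppp1r15a was at 1.39 ± 0.10, Chac1 at 1.15 ± 0.09 and Atf4 at 0.64 ± 0.06. Of the p53 targets 10 rose and 2 fell of 21 tested (11 and 2 adjusted over the list alone, median 0.27, adjusted p = 2.49e-04). Gadd45a was at 1.11 ± 0.05 and Plk2 at 0.92 ± 0.04. For autophagy and lysosome genes 12 rose and 1 fell of 25 tested (13 and 2 adjusted over the list alone, median 0.15, adjusted p = 0.00145). Sqstm1 was at 0.49 ± 0.05 and Gabarapl1 at 0.94 ± 0.11. In the G2/M and mitosis list 1 rose and 15 fell of 27 tested (2 and 16 adjusted over the list alone, median -0.30, adjusted p = 2.51e-07). Cdc20 was at -0.80 ± 0.10, Kif20a at -0.62 ± 0.07 and Cdk1 at -0.36 ± 0.04. For the mitochondrially encoded mRNAs 9 rose and 0 fell of 13 tested (9 and 0 adjusted over the list alone, median 0.32 but 0.00 after quantile normalization, adjusted p = 2.01e-04 but adjusted p = 0.329 with an estimated correlation). Mt-nd3 was at 0.63 ± 0.08 and Mt-nd1 at 0.44 ± 0.06. For ribosomal proteins 18 rose and 0 fell of 79 tested (18 and 0 adjusted over the list alone, median 0.12 but -0.023 after quantile normalization, adjusted p = 5.95e-05 but adjusted p = 0.362 with an estimated correlation). Rplp0 was at 0.24 ± 0.04, but 0.14 and not called with scaling to total reads. In the interferon-stimulated list 1 rose and 6 fell of 16 tested (1 and 8 adjusted over the list alone, median -0.36, adjusted p = 0.0101 but adjusted p = 0.0977 with an estimated correlation). Irf7 was at -0.83 ± 0.09 and Stat2 at -0.66 ± 0.09.

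The model called 2724 genes, 1573 higher and 1151 lower, of which 104 and 18 changed at least 2-fold, against 1521 higher and 2875 lower with scaling to total reads. Without the ES50 libraries in the fit 4716 genes passed limma's threshold, and on thinned reads 1178 did.

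After 50 pulses with PE, mitochondrially encoded mRNAs rose and the YAP targets Cyr61 and Ctgf fell. The medians of the antioxidant and ATF4 response lists rose relative to the median gene, but not with scaling to total reads. Mt-nd3 went from 1199.6 ± 99.6 to 30064 ± 2638 FPKM (4.65 ± 0.08), and Mt-nd1 rose by 4.09 ± 0.06. Hmox1 rose from 149 ± 4.85 to 2003 ± 21.8 FPKM (3.74 ± 0.08, adjusted p = 3.86e-14). Slc7a11 went from 1.58 ± 0.107 to 10.3 ± 0.0901 FPKM (2.13 ± 0.10). Cyr61 went from 112 ± 1.57 to 17.1 ± 1.62 FPKM (-2.65 ± 0.06), and Ctgf and the chemokine receptor gene Ackr3 changed by -2.05 ± 0.07 and -1.87 ± 0.11.

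In these libraries with 48.6% mitochondrial reads, the list of mitochondrially encoded mRNAs was higher: 13 rose and 0 fell of 13 tested (13 and 0 adjusted over the list alone, median 4.02, adjusted p = 1.95e-33). Of the NRF2 targets, 17 rose and 0 fell of 18 tested (18 and 0 adjusted over the list alone, median 0.87 but -0.0014 with scaling to total reads, adjusted p = 3.12e-19). Nqo1 was at 1.31 ± 0.05 and Txnrd1 at 1.30 ± 0.04, and with scaling to total reads 7 rose and 6 fell. Of the ATF4 response genes, 17 rose and 0 fell of 21 tested (17 and 0 adjusted over the list alone, median 0.48 but -0.38 with scaling to total reads, adjusted p = 1.31e-11). Chac1 was at 1.21 ± 0.09 and Trib3 at 1.04 ± 0.08. In the mitochondrial stress list 9 rose and 0 fell of 12 tested (9 and 0 adjusted over the list alone, median 0.31 but -0.55 with scaling to total reads, adjusted p = 7.69e-06). Its member Gdf15, a stress-induced cytokine gene, was at 2.56 ± 0.18, and Mthfd2 and Atf5 were at 0.80 ± 0.08 and 0.66 ± 0.03, but -0.083 and -0.23 with scaling to total reads. In the extracellular matrix list 1 rose and 17 fell of 20 tested (1 and 17 adjusted over the list alone, median -0.32, adjusted p = 3.16e-10). Col3a1 was at -0.43 ± 0.04 and Col1a1 at -0.41 ± 0.03. In the G1/S and DNA replication list 8 rose and 0 fell of 27 tested (8 and 0 adjusted over the list alone, median 0.086 but -0.70 with scaling to total reads, adjusted p = 0.0156). Pcna was at 0.44 ± 0.05, but -0.45 with that scaling, and E2f1 at 0.71 ± 0.10, but -0.073 and not called with it.

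The other 9 called lists lost the call with an estimated correlation. For ribosomal proteins 56 rose and 0 fell of 79 tested (57 and 0 adjusted over the list alone, median 0.31 but -0.58 with scaling to total reads, adjusted p = 3.57e-19 but adjusted p = 0.0696 with an estimated correlation). For complexes II to V 23 rose and 0 fell of 42 tested (28 and 0 adjusted over the list alone, median 0.20 but -0.65 with scaling to total reads, adjusted p = 3.71e-08 but adjusted p = 0.0696 with an estimated correlation), and for complex I 11 rose and 0 fell of 31 tested (13 and 0 adjusted over the list alone, median 0.21 but -0.68 with scaling to total reads, adjusted p = 3.51e-04 but adjusted p = 0.0696 with an estimated correlation). Rplp0 (0.54 ± 0.04), Atp5e (0.59 ± 0.08), Uqcrq (0.55 ± 0.06) and Ndufb7 (0.32 ± 0.07) rose relative to the median gene and fell with scaling to total reads. In the heat shock list 11 rose and 0 fell of 15 tested (12 and 1 adjusted over the list alone, median 0.19 but -0.70 with scaling to total reads, adjusted p = 5.20e-05 but adjusted p = 0.0696 with an estimated correlation). Hspb1 was at 0.33 ± 0.04, but -0.56 with that scaling. Of the smooth muscle markers, 4 rose and 1 fell of 8 tested (4 and 1 adjusted over the list alone, median 0.24 but -0.55 with scaling to total reads and -0.019 after quantile normalization, adjusted p = 0.0184 but adjusted p = 0.0829 with an estimated correlation). Tagln was at 0.35 ± 0.03 and Acta2 at 0.34 ± 0.03, but -0.55 and -0.56 with scaling to total reads and -0.20 and -0.43 after quantile normalization. For ribosome biogenesis 10 rose and 1 fell of 27 tested (10 and 2 adjusted over the list alone, median 0.11 but -0.75 with scaling to total reads, adjusted p = 0.0107 but adjusted p = 0.11 with an estimated correlation). Myc was at 1.70 ± 0.16. Among immediate early genes 10 rose and 4 fell of 26 tested (12 and 6 adjusted over the list alone, median 0.22 but -0.60 with scaling to total reads, adjusted p = 0.0186 but adjusted p = 0.31 with an estimated correlation). Ier3 was at 1.82 ± 0.08, Dusp5 at 1.76 ± 0.06 and Fos at -0.50 ± 0.12. Of the fibroblast markers, 1 rose and 4 fell of 6 tested (1 and 4 adjusted over the list alone, median -0.42, adjusted p = 0.0178 but adjusted p = 0.0696 with an estimated correlation). Col1a2 was at 0.92 ± 0.26, but 0.021 and not called with scaling to total reads. In the interferon-stimulated list 2 rose and 6 fell of 16 tested (2 and 7 adjusted over the list alone, median -0.33, adjusted p = 0.0205 but adjusted p = 0.114 with an estimated correlation). Irf7 was at -0.77 ± 0.09.

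The YAP and SRF targets were not called as a list, where 7 rose and 9 fell of 20 tested (7 and 10 adjusted over the list alone, median -0.14, adjusted p = 0.21). Amotl2 was at -1.68 ± 0.07. Bax was at 0.37 ± 0.06, Sod2 at 0.42 ± 0.05 and Vdac1 at 0.21 ± 0.07, all lower with scaling to total reads. The model called 3370 genes, 1679 higher and 1691 lower, of which 103 and 114 changed at least 2-fold, against 90 higher and 10461 lower with scaling to total reads. Without the ES50 libraries in the fit 5382 genes passed limma's threshold, and on thinned reads 1506 did.

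**Figure D2:**
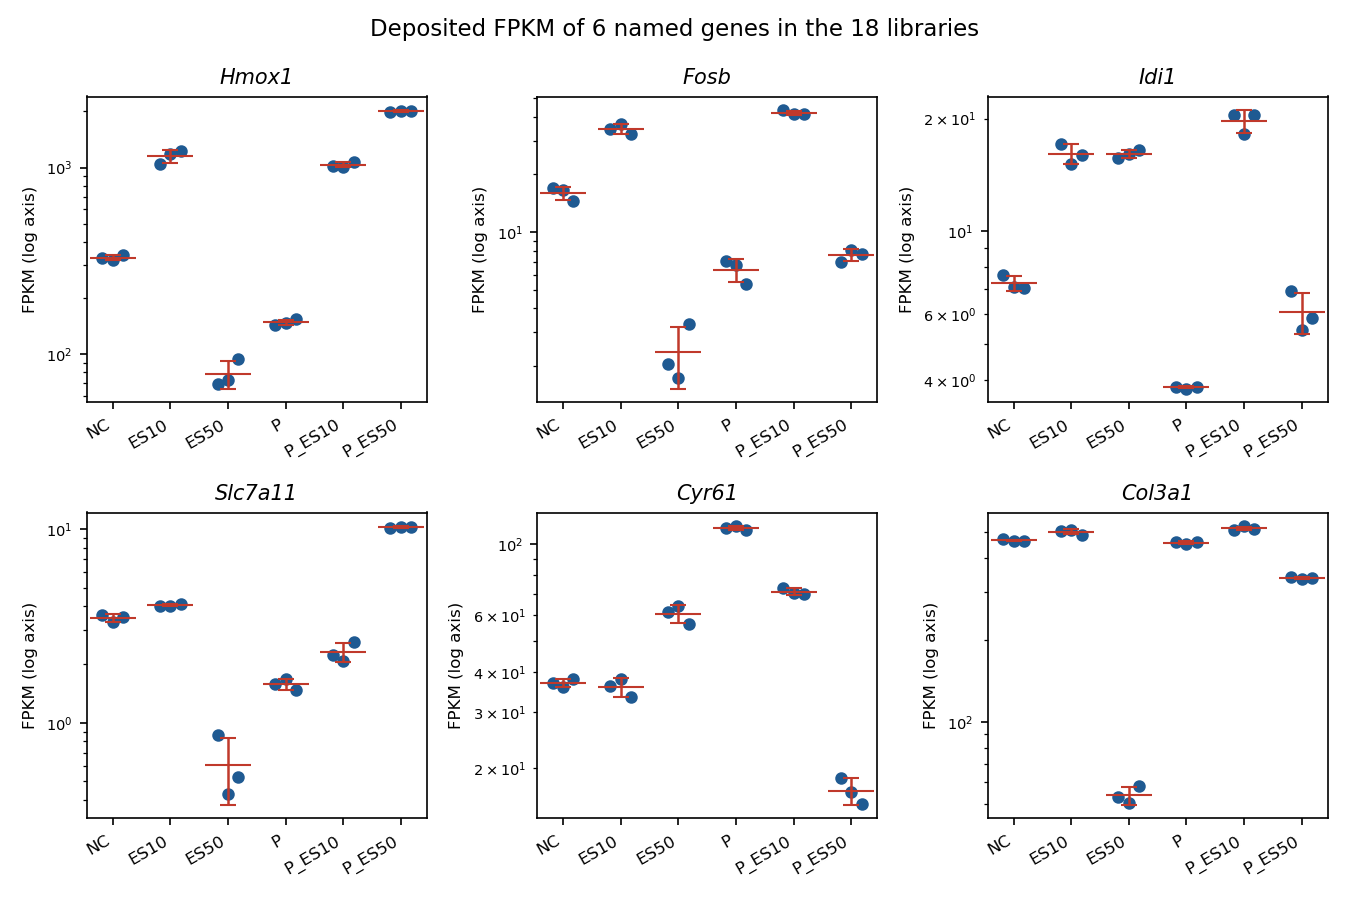
Deposited FPKM (log axis) of Hmox1, Fosb, Idi1, Slc7a11, Cyr61 and Col3a1 in each of the 18 libraries of 6 groups (points), with the group mean and SD (red bars). Hmox1 averaged 329 FPKM in NC, 78.8 in ES50, 149 in P and 2003 in P_ES50, and neither of these directions flipped with scaling to total reads.

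With PE, 50 pulses gave fewer transcripts of cholesterol synthesis than 10 pulses. The median of the antioxidant list was higher relative to the median gene, but lower with scaling to total reads. Hspa1b was at 9.68 ± 0.928 FPKM in P_ES10 and 0.329 ± 0.239 in P_ES50 (-3.02 ± 0.18), Fos at -2.82 ± 0.12, Fosb at -2.32 ± 0.13 and Trim72 at -2.10 ± 0.25. Of the mitochondrially encoded mRNAs, 13 rose and 0 fell of 13 tested (13 and 0 adjusted over the list alone, median 3.65, adjusted p = 2.54e-37). Mt-nd6 was at 4.27 ± 0.10 and Mt-nd3 at 4.02 ± 0.08. Among genes of cholesterol synthesis, 0 rose and 15 fell of 24 tested (0 and 17 adjusted over the list alone, median -0.58, adjusted p = 4.50e-11). Idi1 was at -1.55 ± 0.07 and Hmgcs1 at -1.50 ± 0.05. Of the NRF2 targets, 14 rose and 2 fell of 18 tested (14 and 2 adjusted over the list alone, median 0.43 but -0.37 with scaling to total reads, adjusted p = 4.04e-10). Slc7a11 was at 1.77 ± 0.10, Nqo1 at 1.37 ± 0.05 and Hmox1 at 0.95 ± 0.08, but 0.15 and not called with scaling to total reads. In the mitochondrial stress list 7 rose and 1 fell of 12 tested (8 and 1 adjusted over the list alone, median 0.39 but -0.41 with scaling to total reads, adjusted p = 2.18e-05). Gdf15 was at 2.15 ± 0.18. For fatty acid oxidation 6 rose and 1 fell of 19 tested (6 and 1 adjusted over the list alone, median 0.19 but -0.57 with scaling to total reads, adjusted p = 0.0129). Cpt1a was at 0.92 ± 0.07. In the extracellular matrix list 0 rose and 14 fell of 20 tested (0 and 15 adjusted over the list alone, median -0.30, adjusted p = 2.61e-10). Col3a1 was at -0.60 ± 0.04. The ATF4 and complex I lists were higher, with medians of 0.28 and 0.17 (adjusted p = 4.32e-04 and 1.55e-04), but -0.51 and -0.64 with scaling to total reads. The fibroblast and cardiac hypertrophy lists were lower with both scalings, with medians of -0.43 and -0.27 (adjusted p = 4.32e-04 and 5.04e-04). Ctgf was at -1.68 ± 0.07.

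The other 8 called lists, which lost the call with an estimated correlation, included the immediate early genes, where 3 rose and 13 fell of 26 tested (3 and 13 adjusted over the list alone, median -0.33, adjusted p = 6.55e-04 but adjusted p = 0.157 with an estimated correlation). In the heat shock list 2 rose and 6 fell of 15 tested (2 and 8 adjusted over the list alone, median -0.15, adjusted p = 0.0113 but adjusted p = 0.178 with an estimated correlation). Of the NF-kB and cytokine genes, 2 rose and 6 fell of 15 tested (2 and 7 adjusted over the list alone, median -0.27, adjusted p = 0.0195 but adjusted p = 0.157 with an estimated correlation). Nfkbia was at -1.39 ± 0.15. Of the YAP and SRF targets, 3 rose and 9 fell of 20 tested (3 and 10 adjusted over the list alone, median -0.14, adjusted p = 0.00335 but adjusted p = 0.157 with an estimated correlation). The remaining 4, calcium handling, G2/M and mitosis, complexes II to V and ribosomal proteins, had medians of -0.11, 0.22, 0.18 and 0.19, the last 3 at -0.52, -0.61 and -0.59 with scaling to total reads, with adjusted p = 0.134, 0.0573, 0.0993 and 0.123 with an estimated correlation. The model called 2784 genes, 1249 higher and 1535 lower, against 55 higher and 10348 lower with scaling to total reads. Without the ES50 libraries in the fit 4824 genes passed limma's threshold, and on thinned reads 1246 did.

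Whether PE changed the response to 10 pulses was tested as an interaction, the response with PE minus that without. It was positive for Fos (1.64 ± 0.17, adjusted p = 2.03e-04), Fosb (1.48 ± 0.19) and Egr1 (1.18 ± 0.19), and for Hmox1 (0.99 ± 0.12), Idi1 (1.05 ± 0.11), Hmgcs1 (0.80 ± 0.08) and Gadd45a (0.58 ± 0.07). It was negative for Fhod1 (-0.74 ± 0.10) and Apbb3 (-0.73 ± 0.15). Of the mitochondrially encoded mRNAs, 12 were positive and 0 negative of 13 tested (12 and 0 adjusted over the list alone, median 0.73, adjusted p = 2.00e-36). Mt-nd5 was at 0.64 ± 0.08. Among immediate early genes 5 were positive and 0 negative of 26 tested (14 and 0 adjusted over the list alone, median 0.38, adjusted p = 3.84e-20). Among genes of cholesterol synthesis, 4 were positive and 0 negative of 24 tested (6 and 0 adjusted over the list alone, median 0.16, adjusted p = 3.27e-07). Of the NRF2 targets, 3 were positive and 0 negative of 18 tested (4 and 1 adjusted over the list alone, median 0.18, adjusted p = 2.13e-06), and of the ATF4 response genes 2 were positive and 0 negative of 21 tested (4 and 0 adjusted over the list alone, median 0.33, adjusted p = 2.03e-07). Ppp1r15a was at 0.71 ± 0.14. In the heat shock list 0 were positive and 0 negative of 15 tested (8 and 0 adjusted over the list alone, median 0.18, adjusted p = 3.27e-07). Of the p53 targets 2 were positive and 0 negative of 21 tested (6 and 0 adjusted over the list alone, median 0.17, adjusted p = 1.02e-05). In the G2/M and mitosis list 0 were positive and 0 negative of 27 tested (0 and 3 adjusted over the list alone, median -0.16, adjusted p = 5.46e-06). Calls for ribosomal proteins, skeletal myoblast markers, extracellular matrix, muscle differentiation and the unfolded protein response of the ER, with medians of 0.10, 0.35, -0.061, 0.18 and -0.12, were lost, with adjusted p = 0.239, 0.0928, 0.239, 0.21 and 0.105 with an estimated correlation.

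In limma's model 108 genes had an interaction of PE and 10 pulses, 67 positive and 41 negative, against 94 positive and 171 negative with scaling to total reads. On thinned reads 24 did, and without the ES50 libraries in the fit 561. The count was 63 or 67 without NC replicate 1 or 2, 69, 70 or 66 without ES10 replicate 1, 2 or 3, 71 without P replicate 1 and 61 without P_ES10 replicate 1.

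The responses to 10 pulses with and without PE went the same way for most genes that passed in both. Across 11917 genes, which are not independent replicates, the fold changes correlated with Pearson's r = 0.588 and Spearman's rho = 0.649. Of the genes called in both responses, 665 were higher in both, 219 lower in both and 10 opposite, where independent lists would give 100.05, 25.4 and 107.9. For 50 pulses r was 0.370 and rho 0.325, with 1053 higher in both, 1163 lower in both and 683 opposite, against 535.7, 678.4 and 1213.1. Without the mitochondrially encoded genes r was 0.291 and rho 0.320 for 50 pulses, with 683 opposite. For 10 pulses r was then 0.596 and rho 0.654, with 2 opposite. Both responses share no libraries.

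The interaction of PE and 50 pulses was positive for stress, cytokine and matrix genes and negative for the YAP targets Cyr61, Ctgf and Ankrd1. Hmox1 had the largest value, at 5.80 ± 0.12 (adjusted p = 1.24e-14), and Cxcl1 was at 5.74 ± 0.66, Adm at 5.34 ± 0.11 and Lif at 5.27 ± 0.18. Slc7a11 (3.61 ± 0.14), Txnrd1 (2.64 ± 0.05), Nqo1 (2.41 ± 0.07), Col3a1 (2.66 ± 0.06) and Fn1 (2.25 ± 0.04) were positive. Ctgf (-3.64 ± 0.10), Cyr61 (-3.35 ± 0.09) and Ankrd1 (-3.18 ± 0.08) were negative with both scalings, and Acta2 (-0.99 ± 0.05) and Rplp0 (-1.19 ± 0.05) were negative but positive with scaling to total reads. Mt-nd1 was at -2.55 ± 0.09, but 0.09 without a call with that scaling and 2.11 after quantile normalization.

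In the extracellular matrix list 19 were positive and 1 negative of 20 tested (19 and 1 adjusted over the list alone, median 2.03, adjusted p = 5.04e-11). Of the NF-kB and cytokine genes, 14 were positive and 0 negative of 15 tested (14 and 0 adjusted over the list alone, median 1.73, adjusted p = 4.45e-06). Of the ATF4 response genes, 19 were positive and 1 negative of 21 tested (19 and 1 adjusted over the list alone, median 1.29, adjusted p = 4.61e-08), and of the NRF2 targets 12 were positive and 4 negative of 18 tested (12 and 4 adjusted over the list alone, median 0.91, adjusted p = 0.00768 but adjusted p = 0.12 with an estimated correlation). Among hypoxia targets 11 were positive and 1 negative of 14 tested (11 and 1 adjusted over the list alone, median 1.56, adjusted p = 6.14e-05). Of the fibroblast markers, 6 were positive and 0 negative of 6 tested (6 and 0 adjusted over the list alone, median 1.75, adjusted p = 8.67e-04). For the mitochondrially encoded mRNAs 0 were positive and 13 negative of 13 tested (0 and 13 adjusted over the list alone, median -2.38 but 0.27 with scaling to total reads and 0.36 after quantile normalization, adjusted p = 5.04e-11 but adjusted p = 0.0582 with an estimated correlation). For ribosomal proteins 0 were positive and 70 negative of 79 tested (0 and 72 adjusted over the list alone, median -0.96 but 1.66 with scaling to total reads, adjusted p = 3.98e-21). For complex I 0 were positive and 27 negative of 31 tested (0 and 27 adjusted over the list alone, median -0.90 but 1.68 with scaling to total reads, adjusted p = 1.30e-08). Of the YAP and SRF targets, 3 were positive and 17 negative of 20 tested (3 and 17 adjusted over the list alone, median -1.14 but 1.49 with scaling to total reads, adjusted p = 5.06e-08). In all, 7036 genes had an interaction in limma's model, 3706 positive and 3330 negative, against 10572 and 19 with scaling to total reads.

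Of the 20 genes fixed in advance, 5 were too low to be tested in any comparison. Their highest FPKM in a library were 0.176 for Nppa, 0.033 for Myh7, 0.988 for Ppargc1a, 0.032 for Mfn2 and 0.128 for Hspa1a. Markers of endothelial cells, macrophages and adult cardiomyocytes could not be tested as lists, with 1, 1 and 2 members above the filter.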

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

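The tests of explanations and of other splits in this part were chosen after the results were seen, except the comparison of families of membrane and cytosolic proteins, whose outcome was stated before it was computed. The results listed first differ between the responses to pulses with and without PE, by the interaction in limma's model. For 10 pulses 108 genes did. The median interaction was 0.73 for mitochondrially encoded mRNAs, 0.18 for NRF2 targets, 0.17 for p53 targets, 0.33 for ATF4 response genes, 0.18 for heat shock genes, 0.38 for immediate early genes, -0.16 for G2/M genes and 0.16 for cholesterol genes. Among genes fixed in advance it was 1.64 for Fos, 1.18 for Egr1 and 0.99 for Hmox1, and it was called for 32 of the 119 tested genes named in the text. For 50 pulses 7036 genes differed. The median interaction was 1.75 for fibroblast markers, 2.03 for the extracellular matrix, 1.73 for NF-kB and cytokine genes, 1.56 for hypoxia targets, 1.29 for ATF4 response genes, 0.71 for the unfolded protein response of the ER and 0.69 for ribosome biogenesis. It was -0.88 for smooth muscle markers, -0.90 for complex I, -0.75 for complexes II to V, -1.14 for YAP and SRF targets and -0.96 for ribosomal proteins, and these 5 turned positive with scaling to total reads. Among genes fixed in advance it was 5.80 for Hmox1, 1.89 for Atf3, 1.53 for Bcl2, 1.09 for Ddit3, 0.76 for Egr1, 0.71 for Cdkn1a, 0.42 for Sod2 and 0.37 for Dnm1l. It was -1.02 for Fos, -0.66 for Bax and -0.34 for Acta1, which turned positive with scaling to total reads (1.40, 1.91 and 1.93). It was called for 106 of the 119 named genes.

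Groups of 3 against 3 make 10 splits, too few for a share under 0.05. The real split, counted as 1 of 10, gave 1021 genes for ES10 versus NC, 8583 for ES50 versus NC, 8853 for ES50 versus ES10, 1136 for P versus NC, 2724 for P_ES10 versus P, 3370 for P_ES50 versus P, 2784 for P_ES50 versus P_ES10, 215 for P_ES10 versus ES10 and 8294 for P_ES50 versus ES50. The highest other split gave 1, 0, 1, 1, 1, 2, 1, 1 and 6 genes. For the interaction of PE and 10 pulses, 6 of 100 splits gave at least the 108 real genes, the highest 246. The 5 others, with 145 to 246 genes, kept the NC and P libraries in place and exchanged 2 ES10 libraries for P_ES10 libraries. They carry the real difference between P and NC, a structure of the samples, which raises their counts, so whether chance can be excluded is not settled here. For the interaction of PE and 50 pulses, 1 of 100 splits, the real one, gave 7036 genes. The highest other, with 2 NC libraries exchanged for P libraries and all 3 ES50 libraries for P_ES50 libraries, gave 6719. The top splits carry real differences between groups here too, a structure of the samples that raises their counts. All stayed below the real one, but splits with such differences do not measure chance. So whether chance can be excluded is not settled here either.

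The first pattern is the share of mitochondrial reads in ES50 and P_ES50. The deposited scaling is argued against, since the share of recovered reads needs no scaling and its lowest value in the 6 libraries was 46.7%. For a failed poly(A) selection, mitochondrial rRNAs, against mitochondrial mRNAs, changed by -0.24 in ES50 and -0.65 in P_ES50 on the log2 scale and did not rise. This cannot decide the question, because the log2 ratio was already -6.50 in NC and -6.55 in P. Whether rRNA reads were removed before counting is not known here. Of the mitochondrial tRNAs, 17 rose and 0 fell of 19 tested in ES50 versus NC, with a median of 5.20. The ratio of mitochondrial to nuclear reads changed by 6.31 (79.4-fold) in ES50 versus NC and by 4.03 (16.3-fold) in P_ES50 versus P. A loss of nuclear-encoded RNA and a gain of mitochondrial RNA cannot be told apart, because 1 µg of RNA entered every library and no amount per cell was measured, and an effect of the pulses on the cells stays open.

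The second pattern is that matrix, cytokine and ER stress lists were lower in ES50 versus NC while ribosomal protein and nuclear OXPHOS lists were higher, relative to the median gene (all lower with scaling to total reads). Gene length as the whole cause is argued against. The median of the 54 genes of the lower lists was -1.45 ± 0.18 (± SE across genes) before and -1.21 ± 0.18 after adjustment for length. That of the 152 genes of the higher lists was 1.15 ± 0.05 and 0.84 ± 0.06. Genes are not independent replicates, so this SE, used here and for the third pattern, does not measure the spread between libraries. The low nuclear depth of ES50 is argued against by the same medians on thinned reads, -1.46 ± 0.19 and 1.17 ± 0.06. A candidate explanation is that mRNAs translated at the ER were lost more than those translated in the cytosol. In gene families outside the lists, adjusted for length and NC level, 220 genes of membrane and secreted proteins lay -1.04 ± 0.08 from 187 of cytosolic and nuclear proteins. Of these, 178 and 36 fell and 14 and 117 rose, and the same difference was -0.26 ± 0.04 in P_ES50 versus P and 0.03 ± 0.02 in ES10 versus NC. The membrane and secreted families include collagens, laminins and ADAM and ADAMTS genes, which are close to the matrix list. In ES50 versus NC each of these families had more lower than higher genes. Of the cytosolic and nuclear families, only hnRNPs and SR proteins did, with 14 lower and 8 higher.

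The third pattern is that most NRF2 and ATF4 genes were higher in P_ES50 than in ES50. Of the ATF4 response genes, 17 rose and 1 fell of 21 tested (17 and 1 adjusted over the list alone, median 0.98, adjusted p = 2.97e-05), and of the NRF2 targets, which were not called as a list, 12 rose and 4 fell of 18 tested (12 and 4 adjusted over the list alone, median 0.62, adjusted p = 0.0594). The low nuclear depth of ES50 is argued against, since the median interaction of the 38 genes of both lists together was 1.28 ± 0.28 (± SE) with all reads and 1.17 ± 0.28 on thinned reads. RNA of P_ES50 as a mixture of P-like and ES50-like RNA is argued against for a part of these genes and stays open for the others. As shares of total reads, 23.7% of the 38 genes (9 genes) lay in all 3 P_ES50 libraries above all P and ES50 libraries, against 0.581% of 11883 nuclear genes and 1.19% by chance. Pooled over both lists, that share lies between what a mixture and its absence were taken to need. Of these 9 genes only Slc7a11 and Chac1 are in the ATF4 list, and Slc7a11 is in the NRF2 list as well. The rest of the 9 are all in the NRF2 list, so the pooled share describes neither list alone. Against P_ES10 and ES50 the pooled share was 13.2% (5 genes), and 0.303% over all nuclear genes. A mixture cannot lie above both of its parts, so these 9 and 5 genes argue against the mixture in question as the whole cause, for these genes only. For the other genes of the 2 lists neither mixture can be told apart from an effect of PE on the response of the cells.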

How the results depend on the processing

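Total-read scaling, limma-voom, thinned reads, protein-coding genes only for counts and lists, and the fit without ES50 libraries were chosen after the data were seen. Counts of changed genes stayed within 1.5 times of the reported value in 106 of 139 settings. With only the groups compared in the fit they were 2246 for ES10 versus NC, 2724 for P versus NC, 4708 for P_ES10 versus P, 693 for the interaction of PE and 10 pulses and 877 for P_ES10 versus ES10. The fit without the 3 ES50 libraries gave 2574, 3200, 4716, 561 and 1100 for these 5, and 5382 for P_ES50 versus P and 4824 for P_ES50 versus P_ES10, and every gene of the reported counts was among them. With limma-voom they were 2834, 3533, 5090, 788 and 1363 for the same 5, and 4415 for P_ES50 versus P_ES10. With total-read scaling they were 1681, 2989, 4396, 265 and 478 for those 5, 10551 for P_ES50 versus P, 10403 for P_ES50 versus P_ES10 and 10591 for the interaction of PE and 50 pulses. Thinned reads gave 313, 299, 1178, 24 and 35 for those 5, 1506 for P_ES50 versus P and 1246 for P_ES50 versus P_ES10, where fewer reads are the cause. Leaving groups out of the fit did not move the fold changes (median shift 0), so the estimate of the spread and its degrees of freedom are the cause there. For limma-voom and total-read scaling the cause was not tested. Rescaling by median ratios multiplies all values by 1 constant and so tests no scaling, though it is among the 139 settings.

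The replicate block gave 909 genes for ES10 versus NC, 8567 for ES50 versus NC, 8832 for ES50 versus ES10 and 1021 for P versus NC. It gave 2628 for P_ES10 versus P, 3296 for P_ES50 versus P, 2695 for P_ES50 versus P_ES10, 104 and 6973 for the interactions with 10 and 50 pulses, 181 for P_ES10 versus ES10 and 8289 for P_ES50 versus ES50. Same-numbered libraries deviated together with r of -0.0879 to 0.101 across genes over 45 pairs, and 7 of 18 libraries correlated best with their own number, so the numbers were not taken as pairs.

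With each library left out in turn, fewer samples are the cause of lower counts. They ran from 580 to 650 for ES10 versus NC, 8101 to 8789 for ES50 versus NC, 8376 to 8982 for ES50 versus ES10 and 626 to 763 for P versus NC. They were 1931 to 2107 for P_ES10 versus P, 2510 to 2797 for P_ES50 versus P and 2055 to 2271 for P_ES50 versus P_ES10. The interactions with 10 and 50 pulses gave 61 to 94 and 6545 to 7506, P_ES10 versus ES10 gave 78 to 98 and P_ES50 versus ES50 7862 to 8502. Lower by over 1.5 times were ES10 versus NC without NC replicate 1, 2 or 3 (650, 584 and 580) or ES10 replicate 1, 2 or 3 (617, 588 and 613), P versus NC without NC replicate 1, 2 or 3 (626, 682 and 698) or P replicate 1 or 2 (627 and 631), and P_ES10 versus ES10 without any 1 of its 6 libraries (78 to 98). So was the interaction with 10 pulses without NC replicate 1 or 2 (63 and 67), ES10 replicate 1, 2 or 3 (69, 70 and 66), P replicate 1 (71) or P_ES10 replicate 1 (61). The correlation across genes of the responses with and without PE ran from 0.540 to 0.579 for 10 pulses and 0.346 to 0.384 for 50 pulses. For 10 pulses it was 0.429 with a pseudocount of 0.1, 0.850 over genes called in either response and 0.307 on thinned reads.

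Over the 9 contrasts fixed in advance, camera made 139 list calls at the preset correlation, of which 84 held with an estimated correlation, and fry called 233. Single list results kept direction and side of the threshold in 763 of 834 settings and lost the call in 71, and with a library left out in 995 and 25. Named genes did so in 1476 settings, lost the call in 39 and gained it in 3, and with a library left out in 1683, 49 and 2. These counts of lists and named genes leave out total-read scaling and quantile normalization, so calls lost with those 2 are not among them. The 834 list settings include rescaling by median ratios, whose agreement was nearly fixed in advance. Quantile normalization was fixed in advance for the counts of changed genes, and its use for lists and named genes was added after the data were seen. Compared by direction, total-read scaling and quantile normalization flipped 49 and 6 of 172 called list results and 36 and 5 of 250 called results of named genes. Over protein-coding genes only, the 10 most abundant genes rose in their share of FPKM by 70.6 points in ES50 versus NC and 53.7 in P_ES50 versus P, and ribosomal protein genes changed by -6.33 and -4.41 points. The number of genes with an FPKM of at least 1 changed by -5 in ES10 versus NC (38 over all genes), -494 in ES50 versus NC, 41.7 in P_ES10 versus P and -140 in P_ES50 versus P, where fewer genes counted are the cause. Without P replicate 2 the ribosomal protein share of FPKM in P_ES10 versus P turned to -0.0623 points, and the range over left-out libraries was -0.0623 to 0.240. Depth limits ES50 most, with 1230554 to 1466851 nuclear reads, and a gene listed at 0 there was not detectable at this depth.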

Other observations

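The comparisons of PE-treated with untreated cells after the same pulses and the test in the last paragraph were chosen after the data were seen. After 10 pulses, cells with PE differed from those without by higher YAP and SRF targets and lower mitochondrially encoded mRNAs. Cyr61 was at 0.97 ± 0.06, Ctgf at 0.62 ± 0.07, Postn at 1.06 ± 0.10 and Trim72 at 1.10 ± 0.25 on the log2 scale, and the glycine transporter gene Slc6a9 at -0.73 ± 0.07. Of the YAP and SRF targets, 5 rose and 0 fell of 20 tested (7 and 0 adjusted over the list alone, median 0.076, adjusted p = 2.92e-11). Of the mitochondrially encoded mRNAs, 0 rose and 12 fell of 13 tested (0 and 13 adjusted over the list alone, median -0.61, adjusted p = 1.54e-33), with Mt-nd5 at -0.67 ± 0.05. Of the ATF4 response genes, 0 rose and 5 fell of 21 tested (2 and 8 adjusted over the list alone, median -0.086, adjusted p = 8.02e-05), with Psat1 at -0.43 ± 0.04. In limma's model 215 genes differed, 82 higher and 133 lower with PE, against 326 and 152 with scaling to total reads, which moved the median gene by 0.06. The count was 98, 81 or 94 without ES10 replicate 1, 2 or 3, and 80, 78 or 97 without P_ES10 replicate 1, 2 or 3.

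After 50 pulses 8294 genes differed between cells with and without PE, 4494 higher and 3800 lower, against 11107 and 35 with scaling to total reads, which moved the median gene by 1.80. The chemokine gene Cxcl1 was at 5.26 ± 0.47, Lif at 4.79 ± 0.13, Hmox1 at 4.66 ± 0.08 and Adgre5 at 5.25 ± 0.22, while Ankrd1 was at -3.18 ± 0.06. The share of mitochondrial reads differed as well, at 48.6% in P_ES50 and 92.1% in ES50. In the extracellular matrix list 19 rose and 0 fell of 20 tested (19 and 0 adjusted over the list alone, median 2.09, adjusted p = 1.31e-10). Of the NF-kB and cytokine genes, 15 rose and 0 fell of 15 tested (15 and 0 adjusted over the list alone, median 1.73, adjusted p = 2.98e-06). For ribosomal proteins 0 rose and 72 fell of 79 tested (0 and 72 adjusted over the list alone, median -1.0 but 1.69 with scaling to total reads, adjusted p = 1.23e-21).

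Reads on genes of small nucleolar RNAs (snoRNAs), which guide chemical modification of ribosomal RNA, were lower in ES50. Mature snoRNAs have no poly(A) tail, so these poly(A) libraries do not measure their amount. Of 266 tested snoRNAs, 176 fell and 2 rose in ES50 versus NC, with a median of -1.68. With scaling to total reads the median was -2.41. That scaling moved the median gene by -2.49, so this value does not set snoRNAs apart from other genes. Whether the low nuclear depth of ES50 lowers the values of snoRNAs and other small RNAs was not tested. The 10 largest decreases of that comparison under the rule for named genes were 9 snoRNAs and Adgre5. Summed over 3 libraries, SNORD79 had 344 reads in NC and 0 in ES50, SNORD25 215 and 0, SNORD29 1136 and 3, SNORD44 907 and 4 and SNORA7 278 and 0, which are reads as recovered, not scaled for depth. In P_ES50 versus P 36 fell and 11 rose, with a median of -0.33. Other small RNAs also had medians below 0 in ES50 versus NC, with 87 of 199 microRNAs lower and 8 higher (median -0.91). The values were 38 and 8 of 116 for small nuclear RNAs (-0.69), 10 and 0 of 22 for miscellaneous RNAs (-0.72) and 8 and 0 of 18 for rRNAs (-0.96). Over all 11917 tested genes 4781 were lower and 3802 higher (-0.13). These classes thus differed more by few higher calls than by many lower ones. Mitochondrial tRNAs went the other way, with 0 lower and 17 higher of 19 (5.20). Of the 13 mitochondrially encoded mRNAs, Mt-nd4l, Mt-nd4 and Mt-nd5 were chosen here after their values were seen. They are neighbours on the mitochondrial genome (9870 to 13565) and rose less, by 3.83 ± 0.09, 5.30 ± 0.21 and 4.63 ± 0.05 in ES50 versus NC, where the other 10 lay between 5.57 and 7.16. In P_ES50 versus P they rose by 1.45 ± 0.09, 2.99 ± 0.21 and 2.19 ± 0.05, and the other 10 by 3.48 to 4.65.

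A hypothesis on the larger response to 10 pulses with PE is that the difference lies before the pulses, in the different starting level of these genes in P. Of the 108 genes with an interaction, 92 (85.2%) differed more between P and NC than between P_ES10 and ES10, with a median absolute log2 difference of 0.49 before and 0.15 after the pulses. Of the 108, 96 were called between P and NC and 36 between P_ES10 and ES10. This may be read as a shared end level rather than a stronger response, but all 4 groups enter the choice of these genes.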
